A study of Mus musculus with 50 samples.

How the data were processed

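The libraries were made from mouse kidney tissue taken by laser capture microdissection or from whole kidney. Per the labels, RNA came from an Ambion RNAqueous Micro kit, had RIN values above 8, and 200 ng to 1 µg of it went into poly-A libraries made with Illumina TruSeq kits. The submitters' processing notes name HTSeq 0.6.1 and the mm9 genome. The aligner and the gene annotation are not given in the sources used here. The labels do not say how a region was chosen for capture, nor the mouse strain or the hour at which tissue was taken.

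The deposited files hold, per the file headers, a count of reads per gene for each library and an FPKM value per gene in the column layout of Cufflinks gene tracking. The count table has 50 libraries and 23284 gene symbols, of which 22987 have a single position and 23235 also stand in the FPKM files. The 50 FPKM files each matched the counts of their own library better than those of any other (lowest correlation 0.963 over 13833 genes). Ren1 and 49 further genes had at most 5 counts in any library and a mean FPKM above 10, so Ren1 was read from the FPKM values, on the log2 scale with 0.1 added, with exact permutation tests.

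Counts were analysed in R 4.3.3 with edgeR 4.0.16. In each region the libraries of all 3 arms were fitted together after filterByExpr and TMM scaling, with robust quasi-likelihood fits and F tests, and p values were adjusted by the Benjamini-Hochberg method at 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. Differences of a change between regions were tested in 1 fit of the 33 cortex, OSOM and ISOM libraries with each animal as a block, so CPM values differ slightly from those of the regional fits. Glomeruli had 2 libraries per arm and were fitted alone.

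Before the data were examined, 32 gene lists were written from general knowledge, the comparisons and the other settings were set down, and 10 genes (Lcn2, Havcr1, Clu, Fos, Slc34a1, Umod, Aqp2, Ren1, Pck1 and Pdk4) were chosen for display in every comparison. The list tests used camera with its preset correlation of 0.01, and a second run estimated the correlation from the data. Adjustment was over the lists of a comparison. Of 480 list tests between arms, 216 passed with the preset correlation and 9 with the estimated one, and the list tests between control regions are outside this tally. The number of genes of a list past the test is given over all genes and, for some lists, also over the list alone. Further named genes are the 5 rising and 5 falling genes with the largest change in each comparison (3 and 3 in whole kidney and glomeruli) among those past the test with a mean log2 CPM of at least 3 and no overlap between the groups, up to 4 members of each list told, and the 5 and 5 with the smallest p for differences between regions. Some genes chosen by these rules are not reported here. No fold change is given where controls had at most 3 counts.

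The other settings were RLE scaling, no filter, DESeq2 1.42.0, limma-voom with quality weights (limma 3.58.1), and a fit of only the 2 arms compared. In others 1 library was left out at a time (1 animal in the fits across regions). The rest were a replicate block (by replicate number), no animal block in the fits across regions, and the estimated correlation. Added after the data were seen were the animal set as a term, each set alone, the library number series as a term, and the set acting differently in each region.

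The steps were tested on simulated data made from the counts with 100 genes changed 2-fold and 100 changed 4-fold. Of these edgeR found 69% and 93% in the iAKI cortex layout (2.94% of calls false), 73% and 98% in the pAKI cortex layout (2.29% false), 74% and 93% in the pAKI OSOM layout (4.02% false), 74% and 95% in the pAKI ISOM layout (4.52% false) and 52% and 97% in the pAKI whole kidney layout (5.10% false). In glomeruli it found 34% and 91% for iAKI (7.04% false) and 42% and 81% for pAKI (10.2% false) against controls, and 6.94% of calls were false for iAKI against pAKI in cortex. DESeq2 had 16.0% false calls in pAKI cortex, 16.2% in pAKI OSOM, 17.9% in pAKI ISOM, 14.5% in pAKI whole kidney, and 19.5% for iAKI and 18.8% for pAKI in glomeruli. In these layouts genes varied independently around the control means, without the animal sets. Far fewer genes changed in them than were called in iAKI outside glomeruli. The rates need not hold for the real comparisons. The libraries were also regrouped within the same counts, in every possible way or, for genes changed the same way, in random draws, and results of these splits are told in the closing section. Extreme single values were sought with a Dixon test among the pAKI libraries for genes shown in the pAKI comparisons. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.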

Results

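Gene expression was measured by RNA-seq in mouse kidney, in regions taken by laser capture microdissection and in whole kidney, to compare 2 models of acute kidney injury with controls. The pAKI animals are called prerenal in the labels, and the iAKI animals carry the code IR10, which the labels do not spell out. Cortex, the outer stripe of the outer medulla (OSOM), the inner stripe of the outer medulla (ISOM) and whole kidney each had 3 control, 5 pAKI and 3 iAKI libraries, and captured glomeruli had 2 of each, 50 libraries in all. The descriptions of the ISOM libraries read inner medulla, and those of the whole kidney libraries carry the word contralateral in every arm. In units of 1e6 counts, library totals lay between 13.26 and 19.16 in glomeruli and between 14.5 and 19.74 in cortex. They lay between 17.04 and 22.35 in OSOM, 16.51 and 23.57 in ISOM, and 17.06 and 30.22 in whole kidney.

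The animals fell into 2 sets that the labels do not name and that were found in the data. Set 1 held Control 3, Control 4 and pAKI 1, 2 and 3. Set 2 held Control 5, pAKI 4 and 5 and all 3 iAKI animals. Nnt, the mitochondrial transhydrogenase, had 400 ± 30.2 counts per 1e6 counts (CPM, mean ± SD, n = 5) in the cortex of set 1 and 120 ± 38.7 CPM (n = 6) in that of set 2, and Wdfy1 had 75.6 ± 6.09 and 25.5 ± 8.47 CPM. The comparisons below therefore also give the number of genes found with the set as a term. For the arms of a region other than glomeruli they also give the number within a set. Set 1 holds no iAKI animal, so its fits lack the iAKI libraries, while those of set 2 hold them. Counts within set 1 and set 2 therefore differ in the arms fitted as well as in the set. All gene values are means ± SD in CPM. Log2 fold changes, their standard errors (SE) and adjusted p come from edgeR, and positions are those of mm9. For a gene list, the numbers in brackets are the genes past the test when adjusted over the list alone, where given, then the adjusted p of the camera test, then that p with an estimated correlation.

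In control animals the captured regions carried the markers of their tubule segments. Slc5a2, the glucose transporter of the early proximal tubule, had 273 ± 56.4 CPM in cortex, 5.63 ± 1.63 CPM in OSOM and 1.66 ± 0.374 CPM in ISOM (n = 3 each). Slc12a1, the Na-K-2Cl cotransporter of the thick ascending limb, had 1009 ± 92.4, 2116 ± 350 and 8538 ± 2243 CPM. Of 26 proximal tubule markers, 26 were higher in OSOM than in ISOM (adjusted p = 1.22e-09, and 0.495 with an estimated correlation). They were led by the fatty acid transporter Slc27a2 with 11020 ± 981 against 323 ± 145 CPM. In the same comparison 12 of 14 thick ascending limb markers (0.000112, estimated 0.441) and 11 of 13 collecting duct principal cell markers (0.000644, estimated 0.296) were lower. OSOM against cortex had 10 of 10 distal convoluted tubule markers lower (adjusted p = 1.52e-14, and 0.0201 with an estimated correlation). It also had 12 of 14 intercalated cell markers lower (2.89e-15, estimated 0.0311). Podocyte markers were lower for 10 of 12 (5.21e-12, estimated 0.0311), such as the transcription factor Wt1 with a log2 difference of -4.92. ISOM against cortex had 24 of 26 proximal tubule markers lower (1.29e-11, estimated 0.277). There 11 of 14 thick ascending limb markers (3.51e-07, estimated 0.277) and 10 of 14 endothelial markers (0.000848, estimated 0.506) were higher. In all, 6077 of 15406 genes differed between OSOM and cortex, 9432 between ISOM and cortex and 9829 between OSOM and ISOM. These numbers were 5594, 9275 and 9343 when the set was allowed to act differently in each region.

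In the cortex of iAKI animals, against controls, Havcr1, Krt20, Lcn2 and Fgg rose, and Hpd, Slc34a1 and Egf fell. Havcr1, the injury molecule KIM-1 (chromosome 11, 46553725 to 46593080), had 679 ± 360 CPM in iAKI and 2.03 ± 2.71 CPM in controls (n = 3 each, log2 fold change 8.33, SE 1.09, adjusted p = 0.0029). Krt20, a keratin (chromosome 11, 99289717 to 99299467), had 438 ± 265 against 0.802 ± 0.650 CPM (9.04, SE 1.07, adjusted p = 0.00208). Lcn2, the iron-binding lipocalin NGAL (chromosome 2, 32240157 to 32243259), had 389 ± 310 against 1.98 ± 0.668 CPM (7.60, SE 0.87, adjusted p = 0.00185). The fibrinogen chain Fgg (chromosome 3, 82811818 to 82818971) rose from 8.94 ± 1.18 to 516 ± 310 CPM (5.85, SE 0.50, adjusted p = 0.000584). Its partner chains Fgb and Fga had log2 fold changes of 6.36 and 4.78. Hpd, an enzyme of tyrosine breakdown (chromosome 5, 123621816 to 123632695), fell from 379 ± 9.03 to 31.1 ± 27.9 CPM (-3.60, SE 0.63, adjusted p = 0.00673). Slc34a1, the phosphate transporter of the proximal tubule (chromosome 13, 55501009 to 55516056), fell from 6178 ± 711 to 2291 ± 1825 CPM (-1.43, SE 0.42, adjusted p = 0.0332). Egf, a growth factor made by the distal nephron (chromosome 3, 129380493 to 129458240), fell from 1920 ± 142 to 370 ± 324 CPM (-2.38, SE 0.54, adjusted p = 0.0152).

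In iAKI cortex, 19 of 24 tubular injury markers were higher (22 over the list alone, adjusted p = 5.48e-19, and 0.409 with an estimated correlation). Among them Clu, the chaperone clusterin (chromosome 14, 66587320 to 66600382), had 3327 ± 3480 against 540 ± 191 CPM. Cytokine and acute-phase genes were higher for 15 of 22 (19, 7.34e-23, estimated 0.189), such as the acute-phase protein Lrg1 (log2 4.69). Immediate early genes were higher for 13 of 19 (15, 9.66e-11, estimated 0.409), such as the transcription factors Fos (4.05) and Egr2 (5.16). So were 7 of 17 Nrf2 target genes (10, 1.45e-06, estimated 0.409), with the detoxifying enzymes Gsta1 (5.41), Cbr3 (3.47) and Nqo1 (1.55). Unfolded protein and integrated stress response genes were higher for 6 of 20 (12, 0.000396, estimated 0.490), with Trib3 (3.07), Asns (2.47) and Xbp1 (1.28), and neutrophil markers for 4 of 7 (6, 0.00322, estimated 0.490).

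Oxidative phosphorylation genes were lower in iAKI cortex for 14 of 26 (19 over the list alone, adjusted p = 5.95e-09, and 0.490 with an estimated correlation), such as Sdhb (-0.90), Cox5b (-0.75) and Cox6c (-0.74). Intercalated cell markers were lower for 6 of 14 (10, 1.50e-05, estimated 0.490), such as Slc26a4, the anion exchanger pendrin (-1.04). Proximal tubule markers were lower for 9 of 26 with 1 higher (1.90e-05, estimated 0.496), and thick ascending limb markers for 4 of 14 (0.00176, estimated 0.539). Among the 7 urothelial markers, 3 uroplakins were lower (0.00226, estimated 0.496), all of them at or below 2.8 CPM in controls. Fatty acid oxidation genes had 3 of 28 higher (0.265), red blood cell markers 0 of 4 (0.940) and adipocyte markers 0 of 8 (0.935). The haemoglobin genes listed had at most 1 count in any library, so the red blood cell test lacks them. Of 14627 genes, 2727 changed, 1499 up and 1228 down. Taking the set as a term gave 2391, 1831 of them shared, and set 2 alone, with 1 control, gave 2. Leaving out 1 library gave between 1012 (without Control 4) and 4477 (without iAKI 3). A fit of only the arms compared and a replicate block each gave fewer than 1012, as the closing section tells. With only the arms compared, fewer genes changed in iAKI than in pAKI cortex.

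The OSOM of iAKI animals had more changed genes than any other region, 6074 of 14399, with 3193 up and 2881 down. Havcr1 reached 2745 ± 1466 CPM against 5.09 ± 2.15 in controls (n = 3 each, log2 fold change 9.06, SE 1.28, adjusted p = 0.000289). Krt20 reached 1404 ± 469 against 0.842 ± 0.638 (10.70, SE 1.53, adjusted p = 0.000306), and Lcn2 1097 ± 620 against 5.08 ± 1.68 (7.74, SE 0.71, adjusted p = 2.81e-05). The matrix phosphoprotein Spp1 rose from 674 ± 86.1 to 33560 ± 12280 CPM (5.64, SE 0.43, adjusted p = 1.04e-05). The neutrophil chemokine Cxcl1 rose from 0.333 ± 0.155 to 74.3 ± 9.65 CPM (7.80, SE 0.68, adjusted p = 2.14e-05). Pck1, the gluconeogenic enzyme, fell from 3510 ± 2430 to 392 ± 337 CPM (-3.16, SE 0.61, adjusted p = 0.00174), and Egf fell from 1896 ± 121 to 170 ± 142 CPM (-3.48, SE 0.53, adjusted p = 0.000473).

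All 20 immediate early genes tested in iAKI OSOM were higher (20 over the list alone, adjusted p = 2.36e-12, and 0.217 with an estimated correlation). Tubular injury markers were higher for 21 of 24 (21, 3.41e-17, estimated 0.217) and cytokine and acute-phase genes for 20 of 23 (20, 5.41e-13, estimated 0.217). Stress response genes were higher for 13 of 20 with 1 lower (13, 6.50e-05, estimated 0.401) and Nrf2 target genes for 11 of 18 with 1 lower (11, 0.000104, estimated 0.224). Among p53 target genes 11 of 16 were higher and 1 lower (13, 0.000204, estimated 0.217), led by the cell cycle inhibitor Cdkn1a at 105 ± 19.7 against 4.62 ± 1.94 CPM. Heat shock genes were higher for 9 of 14 (9, 0.000248, estimated 0.392), such as the chaperone Hspa1b at 105 ± 18.2 against 15.2 ± 5.80 CPM. Osmotic stress response genes were higher for 7 of 13 (8, 0.00890, estimated 0.217). Cell cycle genes were higher for 10 of 24 (10, 0.0132, estimated 0.774), such as the replication factor Mcm5 (log2 3.02).

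On the falling side in iAKI OSOM were 24 of 26 oxidative phosphorylation genes (25 over the list alone, adjusted p = 1.78e-06, and 0.483 with an estimated correlation). Proximal tubule markers were lower for 15 of 26 with 1 higher (0.000191, estimated 0.483), such as the inositol oxygenase Miox (-2.61). Gluconeogenesis and amino acid genes were lower for 7 of 16 with 2 higher (0.0319, estimated 0.670). Circadian clock genes were lower for 8 of 18 with 3 higher (0.0277, estimated 0.217). Cholesterol synthesis genes went both ways, 3 higher and 8 lower of 19 (0.222), among them the sterol demethylase Cyp51 (-2.55). Aqp2, the water channel of the collecting duct (chromosome 15, 99409487 to 99414976), rose from 187 ± 60.7 to 430 ± 138 CPM. When the set was a term 5589 genes changed, 4981 of them shared, and in set 2 alone, with 1 control, 1290.

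In the ISOM of iAKI animals Lcn2, Havcr1 and Car15 rose, and Pdgfra, Abca8a and Egf fell. Lcn2 had 2026 ± 1333 CPM in iAKI and 20.6 ± 2.53 in controls (n = 3 each, log2 fold change 6.62, SE 0.63, adjusted p = 0.000193), and Havcr1 123 ± 77.9 against 4.92 ± 5.65 (4.59, SE 1.14, adjusted p = 0.0202). The carbonic anhydrase Car15 (chromosome 16, 17835369 to 17838279) had 492 ± 130 against 14.9 ± 11.04 (5.06, SE 0.72, adjusted p = 0.00177). The growth factor receptor Pdgfra, carried by fibroblasts, fell from 294 ± 28.2 to 67.8 ± 7.16 CPM (-2.12, SE 0.13, adjusted p = 1.48e-05). The lipid transporter Abca8a fell from 40.3 ± 9.42 to 2.56 ± 1.31 CPM (-3.97, SE 0.42, adjusted p = 0.000211), and Egf from 4428 ± 673 to 388 ± 244 CPM (-3.51, SE 0.49, adjusted p = 0.00108). 

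Injury markers were higher in iAKI ISOM for 11 of 23 (18 over the list alone, adjusted p = 6.74e-08, and 0.463 with an estimated correlation). Cytokine and acute-phase genes were higher for 9 of 21 (13, 7.17e-07, estimated 0.371), and Nrf2 targets for 8 of 17 (10, 5.40e-07, estimated 0.371). Stress response genes were higher for 13 of 20 (16, 3.67e-09, estimated 0.371), such as Manf (1.04) and Pdia6 (1.04) of the endoplasmic reticulum. Endothelial markers were lower for 8 of 14 (9, 1.10e-05, estimated 0.371), such as the growth factor receptor Kdr (-0.99). Lower were also 6 of 16 extracellular matrix and fibroblast genes (8, 2.59e-06, estimated 0.371), 6 of 20 interferon response genes (7, 0.000628, estimated 0.617) and 3 of 8 smooth muscle markers (0.0346, estimated 0.617). Clock genes were lower for 10 of 18 with 4 higher (0.000401, estimated 0.152). The podocyte list had 4 of 12 lower (0.00109, estimated 0.371), such as Tcf21 and Cdkn1c, which cells outside the glomerulus also express. Of 14569 genes, 2844 changed, 1453 up and 1391 down. The fit that had the set as a term gave 2122, 1790 of them shared, and set 2 alone gave 752.

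In whole kidney, Havcr1 had 998 ± 579 CPM in iAKI and 2.56 ± 2.08 in controls (n = 3 each, log2 fold change 8.60, SE 0.98, adjusted p = 0.000267), and Lcn2 556 ± 218 against 4.10 ± 1.01 (7.09, SE 0.44, adjusted p = 1.68e-05). Hpd had 18.0 ± 8.09 against 196 ± 13.1 (-3.45, SE 0.35, adjusted p = 0.000153). Of 24 tubular injury markers, 21 were higher (23 over the list alone, adjusted p = 2.08e-36, and 0.0118 with an estimated correlation). Cytokine and acute-phase genes were higher for 18 of 25 (21, 1.50e-19, estimated 0.0118). Proximal tubule markers were lower for 16 of 26 (19, 7.70e-13, estimated 0.0118), such as the endocytic receptor Lrp2 (-1.66) and the amino acid transporter Slc6a19 (-1.89). Hypoxia and glycolysis genes were higher for 6 of 23 (8, 0.00127, estimated 0.0385), such as the glucose transporter Slc2a1 (1.42). Distal convoluted tubule markers were lower for 5 of 10 (4.04e-05, estimated 0.144) and renin-angiotensin genes for 3 of 12 (0.00837, estimated 0.144). Cell cycle genes were higher for 7 of 24 (4.72e-05, estimated 0.407), collecting duct markers for 4 of 13 (0.0168, estimated 0.280), and macrophage and leukocyte markers for 3 of 17 with 1 lower (0.00649, estimated 0.540). Of 14906 genes, 2554 changed, 1351 up and 1203 down. Adding the set as a term gave 2161, 1722 of them shared, set 2 alone gave 245, and leaving out Control 4 or Control 3 gave 1581 or 1686. Whole kidney libraries of set 2, all 3 iAKI and 1 of 3 control libraries among them, also had less of the nuclear RNA Malat1 than those of set 1 (68.3 to 233 against 310 to 609 CPM) and of Neat1 (90.3 to 384 against 406 to 648 CPM), both chosen after their values were seen.

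In glomeruli, with 2 libraries per arm, 5 genes passed the test between iAKI and controls, all higher and named here after their values were seen. The calcium-binding proteins S100a8 and S100a9 of neutrophils rose, S100a8 from 1.46 ± 0.269 to 39.4 ± 28.4 CPM (log2 fold change 4.74, SE 0.58, adjusted p = 0.0483) and S100a9 from 2.57 ± 0.552 to 66.0 ± 43.4 CPM (4.69, SE 0.51, adjusted p = 0.0437). The plasma copper protein Cp rose from 101 ± 4.35 to 366 ± 103 CPM (1.86, SE 0.23, adjusted p = 0.0437), and the diamine oxidase Abp1 from 0.363 ± 0.0141 to 12.4 ± 5.91 CPM (adjusted p = 0.0437). Havcr1 had 31.5 ± 18.9 CPM in iAKI with at most 1 count in a control library (adjusted p = 0.0437). Neutrophil markers were higher as a list, 2 of 9 (6 over the list alone, adjusted p = 4.40e-15, and 0.290 with an estimated correlation). No gene passed between pAKI and controls by edgeR (1068 at an unadjusted p under 0.05, DESeq2 18, limma-voom 0) or between iAKI and pAKI (1965, DESeq2 357, limma-voom 83). Leaving out 1 library gave between 1 (without Control 4) and 33 (without iAKI 3) genes for iAKI against controls. Each of these fits has an arm of 1 library and takes its spread from the other arms. They gave up to 4 for pAKI against controls (without pAKI 3) and up to 25 for iAKI against pAKI (without iAKI 3). The titles of the glomerular libraries carry another prefix (BK) than the rest (BN). The ribosomal RNA gene Rn45s had the most counts in each of them and in no other library. It took 3.39% of counts in Control 1, 10.1% in Control 4, 3.67 and 3.85% in iAKI 2 and 3, and 7.18 and 7.05% in pAKI 3 and 5. Both control libraries were of set 1 and both iAKI libraries of set 2, so only the pAKI libraries separate arm from set in glomeruli. The set as a term gave 1 gene in place of 5 for iAKI against controls, 0 for pAKI against controls and 1 for iAKI against pAKI. The pAKI 3 library stood apart from the rest of its animal, with Arntl and Dbp near the glomerular controls, as described in the closing observations. If it were mislabelled, the comparisons with pAKI in glomeruli would not hold.

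**Figure D1:**
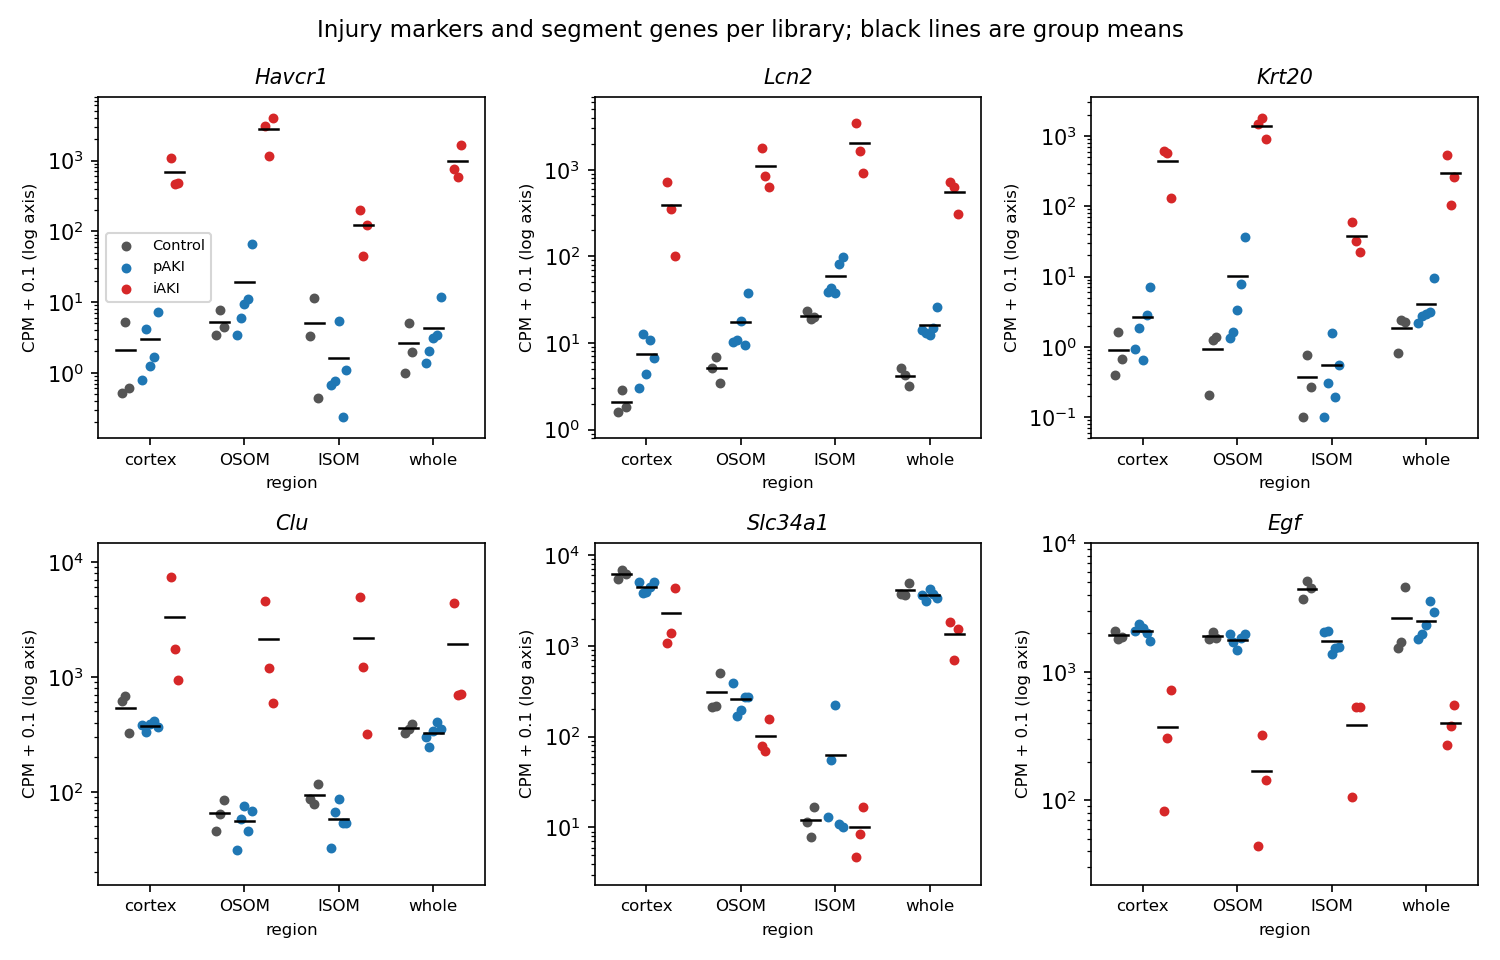
CPM of Havcr1, Lcn2, Krt20, Clu, Slc34a1 and Egf in each library (points; log axis, 0.1 added to each value) by region and arm, with black lines at the group means. Havcr1 averaged 679 CPM in iAKI cortex, 2.93 in pAKI cortex and 2.03 in control cortex.

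In the cortex of pAKI animals, against controls, Arntl, Stc1 and Aqp2 rose, Nkain1 and Cml5 fell, and the list of tubular injury markers had no member past the test. Arntl, the clock activator BMAL1 (chromosome 7, 120350979 to 120457640), rose from 2.28 ± 1.19 CPM in 3 controls to 31.9 ± 17.1 CPM in 5 pAKI libraries (log2 fold change 3.83, SE 0.60, adjusted p = 0.0175). The related activator Npas2 had a log2 fold change of 4.80 (adjusted p = 0.0429). Stc1, a glycoprotein hormone of the kidney (chromosome 14, 69647346 to 69659458), rose from 5.57 ± 1.06 to 59.9 ± 12.6 CPM (3.42, SE 0.46, adjusted p = 0.0135). Aqp2 rose from 245 ± 48.1 to 922 ± 137 CPM (1.91, SE 0.24, adjusted p = 0.00847). Nkain1, which interacts with the sodium pump (chromosome 4, 130125705 to 130169623), fell from 70.7 ± 6.08 to 22.7 ± 2.69 CPM (-1.64, SE 0.15, adjusted p = 0.000388), and Cml5 from 37.6 ± 4.49 to 6.64 ± 2.98 CPM (-2.50, SE 0.32, adjusted p = 0.0115). Havcr1 had 2.93 ± 2.72 against 2.03 ± 2.71 CPM (adjusted p = 0.821) and Lcn2 7.42 ± 4.10 against 1.98 ± 0.668 CPM (adjusted p = 0.206).

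Interferon response genes were lower in pAKI cortex for 5 of 20 (11 over the list alone, adjusted p = 1.48e-10, and 0.147 with an estimated correlation). Among them were Ifit3 (15.5 ± 3.04 against 35.0 ± 10.2 CPM) and the transcription factor Irf7 (-1.07). Macrophage and leukocyte markers were lower for 2 of 17, the chemokine receptor Ccr2 (-1.18) and Aif1 (-1.60) (9, 7.04e-08, estimated 0.147). Osmotic stress response genes were higher for 3 of 13, Aqp2, the amino acid transporter Slc38a2 (1.10) and the taurine transporter Slc6a6 (0.81) (4, 9.94e-08, estimated 0.147). Of 19 immediate early genes 1 was higher, the nuclear receptor Nr4a1 at 52.6 ± 47.1 against 5.98 ± 2.07 CPM (4, 1.79e-07, estimated 0.361). Cell cycle genes had 0 of 22 called and 9 lower over the list alone (5.97e-09, estimated 0.361). Cholesterol synthesis genes had 2 of 19 lower and 8 over the list alone (1.05e-06, estimated 0.361). The injury list had 0 of 24 called, also over the list alone (0.131). Of 14627 genes, 214 changed, 89 up and 125 down. A fit in which the set was a term gave 241, 188 of them shared, set 1 alone (3 against 2) gave 974 and set 2 alone (2 against 1) 0 by edgeR. Each library left out lowered the count, to between 4 (without Control 3 or Control 4) and 142 (without Control 5). DESeq2, limma-voom and a fit of only the arms compared gave more genes, and a replicate block fewer, as the closing section tells.

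In the OSOM of pAKI animals, Arntl rose from 1.28 ± 0.743 to 24.7 ± 13.8 CPM (n = 3 and 5, log2 fold change 4.32, SE 0.61, adjusted p = 0.00939). Cdkn1a rose from 4.62 ± 1.94 to 56.5 ± 41.4 CPM (3.64, SE 0.54, adjusted p = 0.0109), and Aqp2 from 187 ± 60.7 to 554 ± 79.3 CPM (1.57, SE 0.26, adjusted p = 0.0220). Id1, an inhibitor of differentiation, fell from 81.0 ± 57.4 to 13.01 ± 3.91 CPM (-2.64, SE 0.37, adjusted p = 0.00903), and the oxygenase Fmo1 from 500 ± 69.0 to 144 ± 44.5 CPM (-1.80, SE 0.34, adjusted p = 0.0340). Osmotic stress response genes were higher for 4 of 13 (6 over the list alone, adjusted p = 3.89e-09, and 0.0272 with an estimated correlation). These were Aqp2, Slc38a2 (1.08), the kinase Sgk1 (0.94) and Hspa1b (2.07). Macrophage and leukocyte markers were lower for 3 of 17 (11, 1.37e-09, estimated 0.248), Ccr2 (-1.98), Cd3e (-2.10) and Aif1 (-2.16), all at or below 4.36 CPM in controls. Of 20 interferon response genes 1 was lower, Gbp3 at -0.72 (12, 9.02e-10, estimated 0.329). Glucocorticoid response genes were higher for 2 of 16, Cdkn1a and Sgk1 (3, 2.17e-05, estimated 0.329). Immediate early genes had 0 of 20 called but 8 higher over the list alone (1.20e-08, estimated 0.373). Of 14399 genes, 151 changed, 88 up and 63 down. Including the set as a term gave 233, 149 of them shared, set 1 alone gave 918 and set 2 alone 0 by edgeR. Each library left out lowered the count, to between 17 (without Control 3) and 82 (without pAKI 3). A fit of only the arms compared, DESeq2 and above all limma-voom gave more genes. A replicate block gave fewer, as the closing section tells.

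In the ISOM of pAKI animals 953 of 14569 genes changed, 349 up and 604 down. The clock output gene Dbp (chromosome 7, 52960617 to 52965573) fell from 111 ± 6.01 to 5.63 ± 3.74 CPM (n = 3 and 5, log2 fold change -4.29, SE 0.41, adjusted p = 0.00108), and the clock repressor Per3 from 99.0 ± 25.5 to 16.6 ± 7.76 CPM (-2.57, SE 0.34, adjusted p = 0.00259). Arntl rose from 5.71 ± 3.71 to 50.3 ± 15.8 CPM (3.16, SE 0.44, adjusted p = 0.00313). Car15 rose from 14.9 ± 11.04 to 261 ± 130 CPM (4.15, SE 0.67, adjusted p = 0.00794), and the protease Pappa from 15.4 ± 3.16 to 136 ± 42.8 CPM (3.14, SE 0.39, adjusted p = 0.00226). Aqp2 rose from 1069 ± 285 to 2477 ± 518 CPM (1.21, SE 0.29, adjusted p = 0.0282). Umod, the urinary protein uromodulin (chromosome 7, 126606380 to 126622769), fell from 19250 ± 707 to 9594 ± 2293 CPM (-1.004, SE 0.23, adjusted p = 0.0215). The collagen Col1a1 fell from 48.4 ± 7.67 to 15.3 ± 3.595 CPM (-1.66, SE 0.31, adjusted p = 0.0122).

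Clock genes were lower in pAKI ISOM for 10 of 18 and higher for 3 (adjusted p = 9.56e-07, and 0.0367 with an estimated correlation). Extracellular matrix and fibroblast genes were lower for 5 of 16 (12 over the list alone, 2.35e-08, estimated 0.352), with Fn1 (-1.42) and Col1a2 (-1.04). Macrophage and leukocyte markers were lower for 6 of 16 (11, 3.62e-08, estimated 0.164), among them the complement chains C1qa (-1.13), C1qb (-1.005) and C1qc (-1.12). Interferon response genes were lower for 7 of 20 (18, 2.15e-09, estimated 0.352). Cell cycle genes were lower for 2 of 22 (4, 0.00147, estimated 0.655), the cyclin Ccnd1 (540 ± 158 to 148 ± 31.6 CPM) and Mki67 (-2.15). Hypoxia and glycolysis genes were higher for 3 of 23 (4, 0.00147, estimated 0.585), such as the glycolytic enzyme Pfkp (249 ± 29.99 to 530 ± 65.2 CPM). Collecting duct markers went both ways (0.765 over 13 genes), Aqp2 and the transcription factor Gata3 being higher. The sodium channel subunits Scnn1b (-0.57) and Scnn1g (-1.22) and the steroid enzyme Hsd11b2 (-0.78) were lower. The injury list had 0 of 23 called (0.480). Having the set as a term gave 1001 genes, 874 of them shared, set 1 alone gave 472 and set 2 alone 0 by edgeR. The count was 380 without Control 5, 455 without pAKI 4, 459 without Control 4, 460 without pAKI 5 and 534 without pAKI 2. It was higher with DESeq2, limma-voom and a fit of only the arms compared, and lower with a replicate block, as the closing section tells.

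In whole kidney, pAKI against controls, Stc1 rose from 5.88 ± 0.467 to 49.7 ± 10.7 CPM (n = 3 and 5, log2 fold change 3.08, SE 0.23, adjusted p = 0.000185), and Arntl from 2.56 ± 1.34 to 29.7 ± 14.2 CPM (3.50, SE 0.51, adjusted p = 0.0132). Aqp2 rose from 311 ± 116 to 1148 ± 206 CPM (1.88, SE 0.35, adjusted p = 0.0316). Lcn2 rose from 4.10 ± 1.01 to 16.0 ± 5.57 CPM (1.97, SE 0.34, adjusted p = 0.0242), the 1 injury marker of 24 past the test (3 over the list alone, 0.00228, and 0.356 with an estimated correlation). Aldh1a3, an enzyme of retinoic acid synthesis, fell from 23.1 ± 2.96 to 7.12 ± 0.785 CPM (-1.70, SE 0.14, adjusted p = 0.000227). Of 10 distal convoluted tubule markers, 3 that handle calcium fell, Calb1 (-1.49), S100g (-1.44) and Slc8a1 (-1.38) (0.000149, estimated 0.231). Interferon response genes were lower for 3 of 20 (10, 2.12e-10, estimated 0.0947), and macrophage and leukocyte markers for 1 of 17 (14, 5.57e-10, estimated 0.231). Osmotic stress response genes were higher for 2 of 13 (8, 1.25e-08, estimated 0.0947). Of 14906 genes, 162 changed, 70 up and 92 down. Modelling the set as a term gave 269, 161 of them shared, set 1 alone gave 2975 and set 2 alone 7. Each library left out changed the count by more than 1.5 times, from 9 (without Control 3) to 571 (without Control 5). DESeq2, a fit of only the arms compared and above all limma-voom gave more genes, and a replicate block far fewer, as the closing section tells.

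Renin, the enzyme that starts the renin-angiotensin cascade, could not be read from the count table, in which Ren1 had at most 2 counts in any library, so the deposited FPKM values were used for it. Ren1 had 826 ± 341 FPKM in pAKI cortex and 310 ± 22.7 in control cortex (n = 5 and 3, 2.51-fold) and 37.8 ± 8.65 against 13.3 ± 4.72 in OSOM (2.89-fold). It had 55.2 ± 21.5 against 26.5 ± 9.84 in ISOM (2.09-fold) and 350 ± 75.04 against 75.9 ± 22.6 in whole kidney (4.66-fold). In each of the 4, the exact two-sided permutation p was 0.0179, the smallest that 5 against 3 libraries allow (adjusted p = 0.0306 over 12 comparisons). In iAKI Ren1 was lower than in pAKI in cortex (306 ± 30.2 FPKM), ISOM (18.7 ± 7.47) and whole kidney (110 ± 18.2) with the same exact p. In OSOM it had 34.3 ± 10.1 FPKM (exact p of 0.643 against pAKI, and 0.1 against controls, the smallest that 3 against 3 allow).

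**Figure D2:**
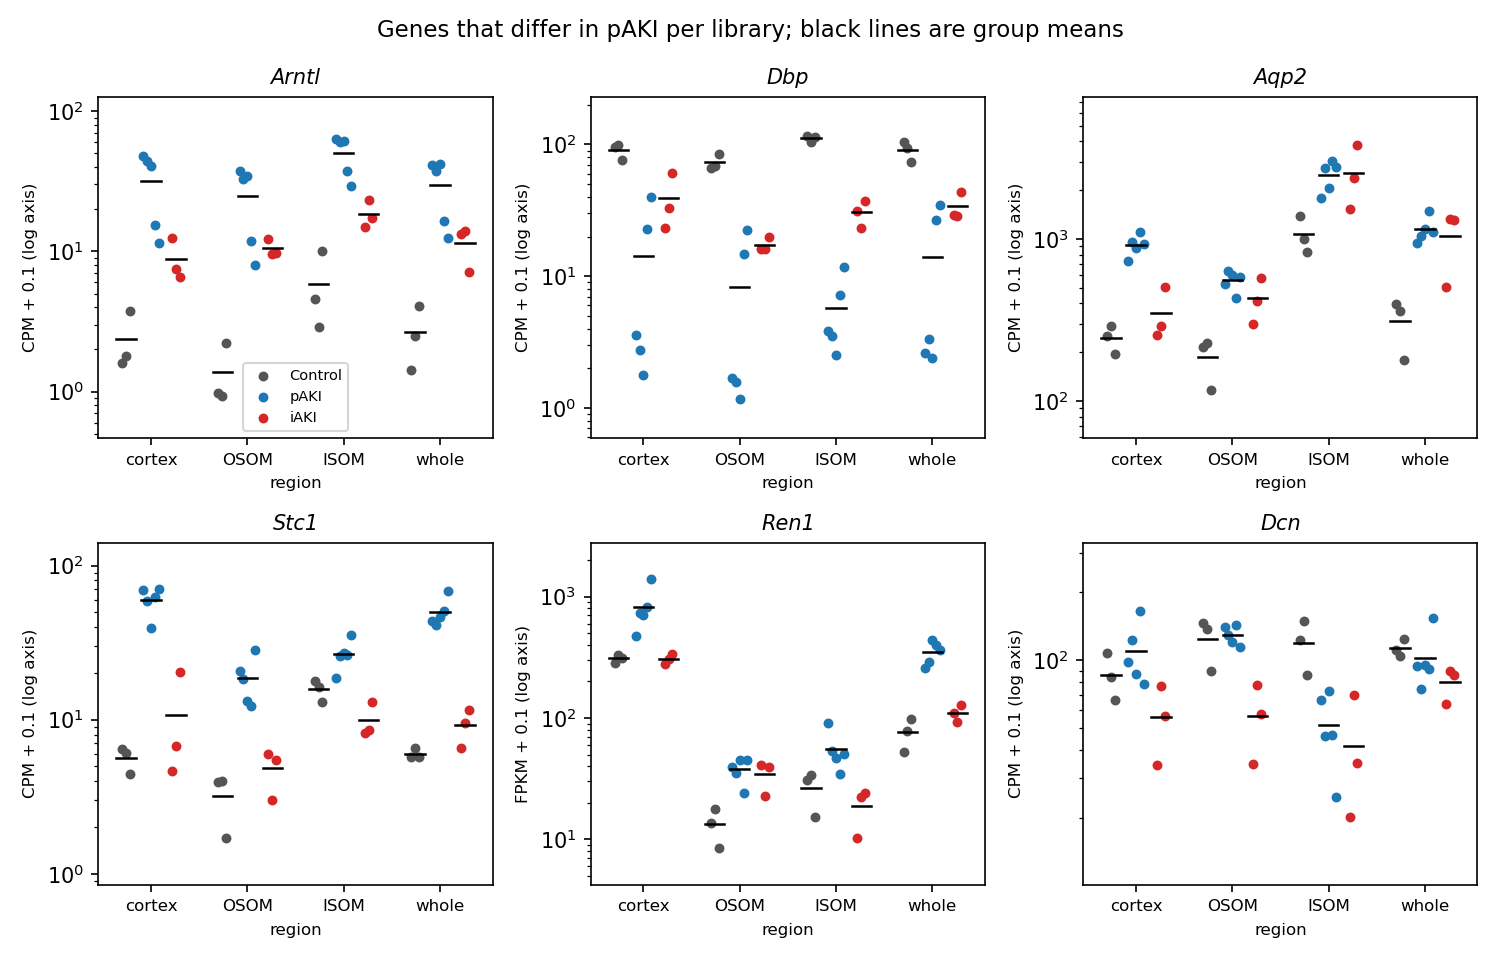
CPM of Arntl, Dbp, Aqp2, Stc1 and Dcn and FPKM of Ren1 in each library (points; log axis, 0.1 added to each value) by region and arm, with black lines at the group means. Arntl averaged 31.9 CPM in pAKI cortex and 2.28 in control cortex, and Aqp2 922 and 245 CPM.

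Between the models, iAKI against pAKI, Havcr1 was higher in iAKI in cortex, OSOM, ISOM and whole kidney. In cortex Havcr1 had 679 ± 360 CPM in 3 iAKI and 2.93 ± 2.72 in 5 pAKI libraries (log2 difference 7.86, SE 0.84, adjusted p = 0.000565), and Hpd 31.1 ± 27.9 against 797 ± 290 CPM (-4.68, SE 0.64, adjusted p = 0.00138). Aqp2 was lower in iAKI, 350 ± 138 against 922 ± 137 CPM (-1.40, SE 0.24, adjusted p = 0.00259). In OSOM Havcr1 had 2745 ± 1466 against 19.3 ± 26.8 CPM (7.15, SE 0.93, adjusted p = 0.000141), and the squamous protein Sprr1a 575 ± 104 against 18.0 ± 9.76 CPM (4.99, SE 0.53, adjusted p = 3.97e-05). The corepressor Tle2 had 12.5 ± 4.46 against 126 ± 21.8 CPM (-3.34, SE 0.23, adjusted p = 4.40e-06). In ISOM Umod had 23410 ± 6115 against 9594 ± 2293 CPM (1.29, SE 0.23, adjusted p = 0.00312), and the metallothionein Mt2 870 ± 1097 against 22.7 ± 13.4 CPM (5.26, SE 1.09, adjusted p = 0.00962). In whole kidney Hpd had 18.0 ± 8.09 against 509 ± 152 CPM (-4.83, SE 0.36, adjusted p = 2.69e-05).

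Injury markers were higher in iAKI than in pAKI for 19 of 24 in cortex, 21 of 24 in OSOM, 16 of 23 in ISOM and 23 of 24 in whole kidney. The camera adjusted p were 7.52e-19, 4.36e-20, 3.44e-13 and 5.14e-34, and with an estimated correlation 0.330, 0.0979, 0.477 and 0.0207. Cell cycle genes were higher for 12 of 22, 17 of 24, 11 of 22 and 19 of 24 (3.28e-06, 0.000820, 6.32e-06 and 2.25e-16, estimated 0.404, 0.684, 0.477 and 0.130). Macrophage and leukocyte markers were higher for 9 of 17, 13 of 17, 10 of 16 and 12 of 17, with 1 lower in each (1.44e-05, 1.94e-05, 0.000189 and 4.39e-12, estimated 0.330, 0.475, 0.477 and 0.130). Among them the lysosomal protein Cd68 had 66.6 ± 7.23 against 3.40 ± 1.97 CPM in OSOM. Oxidative phosphorylation genes were lower for 3, 23 and 22 of 26 in cortex, OSOM and ISOM (0.00457, 7.46e-06 and 2.00e-13, estimated 0.577, 0.511 and 0.477) and for 0 in whole kidney (0.394). In whole kidney 13 of 20 interferon response genes (8.93e-07, estimated 0.130) and 11 of 16 extracellular matrix genes (2.18e-05, estimated 0.235) were higher. There 15 of 26 proximal tubule markers were lower and 2 higher (2.00e-08, estimated 0.0207). In cortex, OSOM, ISOM and whole kidney 3597, 6436, 3205 and 3314 genes differed, and 3266, 5665, 1990 and 3540 did so once the set was a term. Set 2 alone (3 against 2) gave 20, 1358, 5 and 766. Single libraries moved the count by more than 1.5 times in cortex (2045 without iAKI 1, 2120 without iAKI 2), ISOM (1325 without iAKI 1) and whole kidney (2064 without iAKI 3).

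Genes changed the same way by both models numbered 86 in cortex (30 higher and 56 lower), 107 in OSOM (64 and 43), 487 in ISOM (148 and 339) and 80 in whole kidney (36 and 44), with 5, 5, 6 and 2 changed in opposite ways. Aqp2 rose in both models in OSOM, ISOM and whole kidney, and Car15 and Rasd1 in ISOM, where Hlf, Nr1d2, Tcf21, Agtr1a, Col1a2 and Pdgfra fell in both. Both models were compared with the same 3 controls, which cannot be split. The numbers were 73, 162, 438 and 110 in the fit that held the set as a term, and without Control 3 they were 2, 16, 355 and 5. Leaving out 1 library gave 1 to 258 in cortex (highest without iAKI 3), 16 to 270 in OSOM (highest without iAKI 2), 232 to 634 in ISOM and 5 to 232 in whole kidney (highest without Control 5). Independent lists would share 9.12 higher and 10.5 lower genes in cortex, 19.5 and 12.6 in OSOM, 34.8 and 57.7 in ISOM, and 6.34 and 7.425 in whole kidney. In 20 simulations of unchanged arms against the same controls, at most 0, 1, 0 and 0 genes were shared. No gene changed in these arms, so few calls were likely beforehand. How many shared genes the common controls add where many genes change was therefore not measured. On average 68.9 to 69.1% of all genes had the same sign in both simulated arms, against 62.5, 63.4, 65.3 and 60.9% in the data.

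The iAKI change differed between regions for 1213 of 15406 genes between OSOM and cortex, 1204 between ISOM and cortex and 3352 between OSOM and ISOM, in a test of the difference itself with each animal as a block. Plat, the tissue plasminogen activator, had 26.5 CPM in control OSOM and 688 ± 235 in iAKI OSOM, and 224 and 258 ± 45.5 in cortex (log2 difference of changes 4.35, SE 0.30, adjusted p = 3.01e-08). In ISOM it had 131 and 94.2 ± 10.4 CPM (5.14, SE 0.30, adjusted p = 1.48e-09). Havcr1 rose more in OSOM than in ISOM (4.07, SE 1.15, adjusted p = 0.0168) and less in ISOM than in cortex (-3.95, SE 1.17, adjusted p = 0.0471). Clu rose more in OSOM and in ISOM than in cortex (2.44, SE 0.43, adjusted p = 0.00292, and 1.68, SE 0.43, adjusted p = 0.0213). Car15 rose in ISOM, from 12.7 to 410 ± 112 CPM, with 284 and 272 ± 65.4 CPM in cortex (5.42, SE 0.48, adjusted p = 1.05e-05). The kinase gene Mtor had 827 CPM in control OSOM and 174 ± 42.1 in iAKI OSOM, against 89.1 and 83.9 ± 7.39 in ISOM (-2.16, SE 0.21, adjusted p = 9.54e-07). Letting the set act in each region gave 917, 477 and 2704 genes. With 1 animal and all its libraries left out, OSOM against cortex gave between 480 (without iAKI 3) and 1908 (without iAKI 2). ISOM against cortex gave between 525 (without Control 4) and 1289, with 745 without iAKI 1.

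For pAKI the change differed between ISOM and cortex in 1456 genes and between OSOM and ISOM in 374, and between OSOM and cortex in 0 by edgeR (822 at an unadjusted p under 0.05, where chance gives 770, DESeq2 21, limma-voom 54). The tubulin gene Tuba4a had 137 CPM in control and 474 ± 41.5 in pAKI ISOM, and 245 and 190 ± 27.8 in cortex (log2 difference of changes 2.18, SE 0.18, adjusted p = 3.37e-07), with Tubb4b at 1.55 and Tuba1c at 1.46, 3 of the genes named for the smallest p. The proteoglycan Prelp fell in ISOM relative to cortex (-2.12, SE 0.26, adjusted p = 8.72e-05). Umod fell in ISOM relative to cortex (-0.79, SE 0.19, adjusted p = 0.0126) and to OSOM (0.83 for OSOM minus ISOM, SE 0.19, adjusted p = 0.0240). Aqp2 rose less in ISOM than in cortex (-0.69, SE 0.21, adjusted p = 0.0397). A set acting in each region gave 1, 1407 and 379 genes for OSOM against cortex, ISOM against cortex, and OSOM against ISOM. ISOM against cortex gave 642 without pAKI 4, 778 without Control 4, 797 without pAKI 5, 869 without Control 5 and 942 without pAKI 2. OSOM against ISOM gave 53 without Control 5, 127 without pAKI 5, 130 without pAKI 4, 153 without pAKI 2 and 195 without Control 4.

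**Figure D3:**
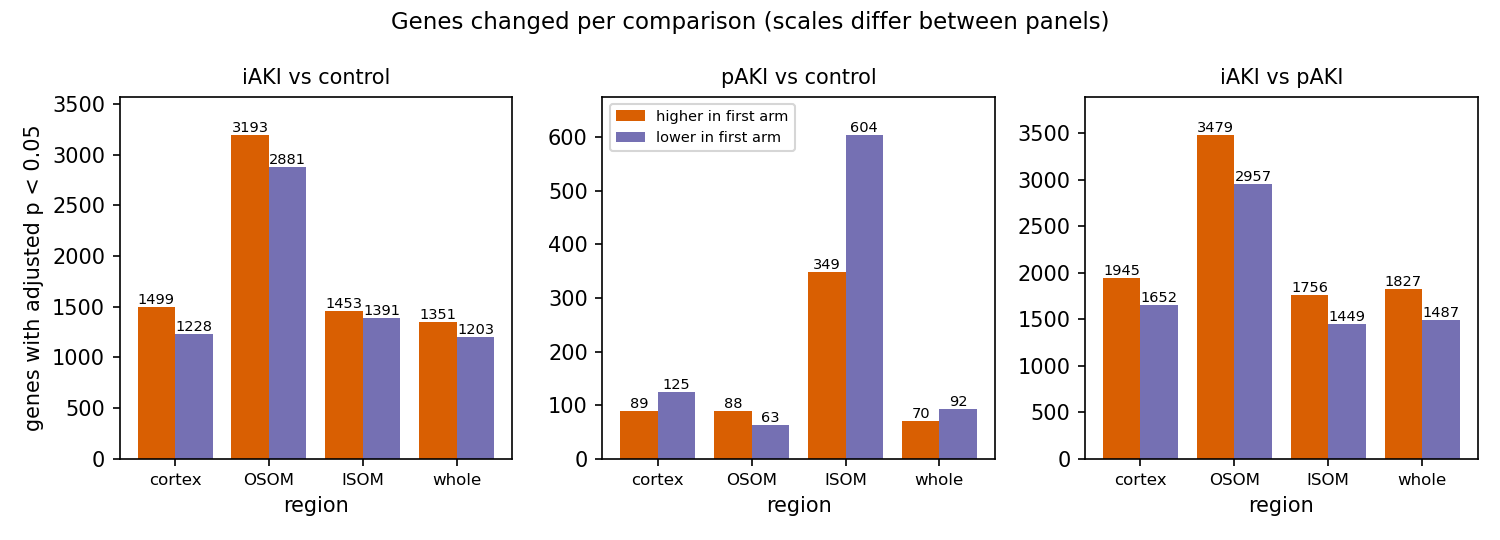
Number of genes past the test (bars from 0; the scale differs between panels), higher and lower, in each comparison and region. The largest numbers are those of iAKI against control (6074) and iAKI against pAKI (6436) in OSOM.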

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

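The tests of explanations in this part, except the 1 that asks whether other pAKI changes follow the clock shift, were chosen after the result they address was seen, so they are tests, not predictions. The differences between regions at the end come from comparisons set down beforehand.

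The 2 animal sets split the arms unevenly, as every iAKI animal is in set 2 and 2 of 3 controls are in set 1. A library batch could produce such a split. A batch that follows the 2 series of library numbers is excluded, since for 4 animals the set differs from the series of their numbers. Other divisions of the numbers were not tested, so a batch with other boundaries is not excluded. Mouse stocks of different origin could also produce it: the sets were found by exploring and sorted by Nnt, Wdfy1 and Entpd4, and Pydc3 and LOC100642166 also differed by set in the other 4 tissues. In glomeruli, 0 libraries fell on the other side for these 2 held-out genes, which fits different stocks, with Pydc3 at 0.0522 CPM in Control 4 and 0.635 in pAKI 3, against 11.8 in iAKI 2, 14.1 in iAKI 3 and 9.29 in pAKI 5. The set term called 235 genes in whole kidney but 11 in cortex, 12 in OSOM and 6 in ISOM, so another difference between the sets, such as in preparation of whole kidney, could add to it and is left open.

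The clock change in pAKI may come from tissue taken at another hour than in controls, or the injury could act on the clock itself. Of 56 pairs of clock gene and region, 51 had a sign that goes with the phase of the gene (49 in iAKI), which cannot tell the 2 apart because the hour of collection is not in the labels. The median ratio of the change in pAKI 4 and 5 to that in pAKI 1 to 3 was 1.13 for called genes outside the clock list (1200 pairs of gene and region, 0.817 in cortex and 1.29 in ISOM) and 0.586 for clock genes (25 pairs). Whether other changes could follow the clock shift is left open, as set 2 has 1 control and the genes were taken as called over all pAKI libraries, which favours genes that keep their change. In cortex Arntl had 39.7 to 48.0 CPM in pAKI 1 to 3, 11.4 and 15.8 in pAKI 5 and 4, 6.53 to 13.3 in iAKI and 1.44 to 3.52 in controls. The glomerular pAKI 3 library lacks the shift of its own animal, with an Arntl minus Dbp distance of 10.3 log2 units from its cortex against 0.647 to 1.116 in 4 other animals. Its Arntl (3.49 CPM) and Dbp (205.7 CPM) lay near the glomerular controls, with 2.89 and 154.5 in Control 1 and 2.14 and 203.4 in Control 4. The glomerular pAKI 5 library had 11.85 and 89.84 CPM. Over 47 pAKI genes outside the clock list the mean change of the pAKI 3 library was 0.256 log2 units. It was 0.166 and -0.166 in the 2 controls, 0.858 in pAKI 5 and 0.273 and 0.542 in iAKI. Whether the pAKI 3 library could be mislabelled is left open with 1 other pAKI library, of the other set, to compare. Its set genes are those of set 1, as in the other libraries of pAKI 3, so only an exchange within set 1 stays possible, which leaves its place in the paragraph above unchanged.

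The fall of matrix and fibroblast genes in pAKI ISOM might come from OSOM tissue in the captured area. Such an admixture would have to reach 47.5%, and in the highest pAKI library proximal tubule markers had 17.5% of their OSOM level, so that explanation is excluded. It may also come from less interstitial tissue of all types, in which case matrix and endothelial genes would fall together. The mean of the matrix genes minus that of the endothelial genes differed between pAKI and controls by -0.696 log2 units (exact two-sided permutation p = 0.0536 over 56 splits, the smallest possible being 0.0179), which cannot tell. The controls lay between -0.180 and 0.105, and of the pAKI libraries only pAKI 3, at -0.155, overlapped them. The rest lay between -1.12 and -0.631. The pAKI 3 library is also the one with the 17.5%. A change within the fibroblasts could give the same values and was not analysed here.

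Every other split of the same libraries into groups of the same sizes was tried, to ask whether as many genes are called when the groups are mixed. A mixed group carries the real difference in its spread, so low counts in mixed splits were likely beforehand. They say little against chance or another factor. In whole kidney the split of pAKI and control libraries that follows the sets called 15 genes, where the set as a term called 235. For iAKI against controls the real counts and the highest of the other splits were 2727 and 0 in cortex, 6074 and 5 in OSOM, 2844 and 0 in ISOM and 2554 and 1 in whole kidney, with 10 splits, too few for a share under 0.05, and 1 of them, the real one, reached the count. For pAKI against controls they were 214 and 11, 151 and 9, 953 and 5, and 162 and 15, and for iAKI against pAKI 3597 and 12, 6436 and 1, 3205 and 11, and 3314 and 118, with 56 splits each, and the split with 118 was pAKI 1 to 3 against the rest, which follows set 1. For the differences between regions they were 1213 and 0, 1204 and 3, and 3352 and 0 in iAKI (10 splits), 1456 and 96 for ISOM against cortex and 374 and 20 for OSOM against ISOM in pAKI (56 splits), and 6077, 9432 and 9829 with 0 between control regions (4 splits, also too few). For pAKI between OSOM and cortex the real count is 0, which 56 of 56 splits reach by construction, so nothing follows from them. For genes changed the same way by both models they were 86 and 0, 107 and 0, 487 and 108, and 80 and 5, with 100 splits drawn at random, the real one included. The draws with 108 and with 5 kept the real controls together and mixed only pAKI with iAKI.

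Among 627 pairs of gene and region, 31.4 would hold an outlying pAKI library at 1 in 20 if values were normally spread. CPM values need not be, and the pairs share the same animals, so an excess over 31.4 says little. Single pAKI values far from the other 4 libraries were found in 45 of the 627 pairs, and 24 of the 45 were in pAKI 3. In cortex these were, in CPM, Ddit4 100.3 (others 36.8 to 48.1), Hspe1 92.78, Sqle 69.0 and Retnlg 0.6606 in pAKI 3, Lnpep 18.09 in pAKI 2, Insrr 49.65 in pAKI 1 and Fga 25.67, the lowest, in pAKI 4. In OSOM they were Fos 22.39 (others 1.56 to 3.43), Dusp1 107.4 and S100a8 1.483 in pAKI 3, Cxcl1 4.353, Il34 19.56, Saa2 0.05121, Myc 7.477 and Tgfb1 23.56 in pAKI 5, Ehd3 49.71 and Tcf21 30.51 in pAKI 4, S100a4 3.155 in pAKI 2 and Sprr1a 2.725, the lowest, in pAKI 1. In ISOM they were Fos 87.43 (others 2.36 to 5.07), Nr4a1 152.0 (others 7.72 to 15.0), Pdk4 221.4, Trpv5 1.659, Retnlg 1.391, Mt1 169.5, Gem 296.3, Myc 18.30, Junb 163.0, Acadm 950.8, Pcx 119.2 and Bhlhe40 162.6 in pAKI 3, and Pparg 7.479 and Egln3 32.96 in pAKI 1, with Pappa 66.74 and Uqcrc2 748.6 the lowest there. In whole kidney they were Fos 28.30 (others 2.00 to 4.16), Atf3 14.02, G6pc 873.5, Wnk1 781.6 and Retnlg 0.7486 in pAKI 3, Lcn2 25.80 (others 12.4 to 14.7) and Krt20 9.297 in pAKI 5, Saa2 0.0453 in pAKI 1, and Bst2 16.88 and, the lowest, Cldn5 15.93 in pAKI 2. Saa2 had 0 CPM in every other pAKI library of OSOM and whole kidney, so its values lie at the floor, where 1 in 20 need not hold. The ISOM library of pAKI 3 also had more proximal tubule signal, with 17.5% of the OSOM level of these markers. The other pAKI ISOM libraries had 3.05 to 7.57%.

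Differences between regions in the log2 change of single genes that passed their test follow. For iAKI, OSOM minus cortex: Clu 2.44, Plat 4.35, Nup93 1.61, Kctd1 1.40, Sdc4 1.45, Anxa2 1.74, Vps8 -1.42, Cnnm4 -1.42, Mtor -1.60, Tmco3 -1.22 and Kcnma1 -2.53. For iAKI, ISOM minus cortex: Havcr1 -3.95, Clu 1.68, Car15 5.42, B830017H08Rik 3.96, Gcsh 1.32, Evc 1.15, Fam20c 1.24, Lox -3.58, Agtr1a -2.28, Cbr3 -2.93, Serping1 -1.22 and Fgfbp1 -2.74. For iAKI, OSOM minus ISOM: Havcr1 4.07, Plat 5.14, Anxa2 2.52, Vasp 1.45, Nes 2.24, Vps8 -1.91, Ogfrl1 -1.43, Mtor -2.17, Tmco3 -1.69 and Trim7 -1.58. For pAKI, ISOM minus cortex: Umod -0.788, Aqp2 -0.689, Pdk4 -0.652, Tuba4a 2.18, Impa1 1.24, Tubb4b 1.55, 1810041L15Rik 5.17, Tuba1c 1.46, Hdac5 -0.9956, Serping1 -1.17, Mxra8 -1.17, Adamts15 -2.20 and Prelp -2.12. For pAKI, OSOM minus ISOM: Umod 0.828, Serping1 0.913, Mxra8 0.964, Nid2 1.38, Tuba4a -1.68, Tmco3 -1.35, Tubb4b -1.36, Impa1 -0.856 and Tfrc -1.90.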

How the results depend on the processing

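The results rest on 3 controls per region (2 in glomeruli), on 1 control in set 2, and on arms that the animal sets split unevenly. The labels do not give the hour, strain or capture rule. Counts of both models move between settings. A gene result is said to stay the same if the gene was past the test in both fits or in neither, whatever the size of its change. A change of sign was counted only for a gene past the test in at least 1 of the fits. Of 1641 gene results, 1630 stayed the same with RLE scaling, 1554 with no filter, 1479 with DESeq2 and 1463 with limma-voom. Of 1383 testable ones 1242 stayed with the set as a term. Of 1171 testable ones, 991 stayed with the library number series as a term, 837 with the replicate block (331 weaker) and 444 with set 2 animals only (723 weaker). The cause of these moves was not tested. Fewer libraries leave fewer degrees of freedom, yet some counts rose with fewer libraries. For pAKI against controls in whole kidney 162 genes changed with all libraries and 571 without Control 5. In log2 CPM, Control 5 there correlated with Control 3 and 4 at 0.956 and 0.962, and these with each other at 0.99. Control 5 is also the only control of set 2. In OSOM it stood apart too (0.976 and 0.977 against 0.993), yet there the count fell without it.

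Counts are given in the order cortex, OSOM, ISOM and whole kidney. With only the 2 arms compared, iAKI against controls gave 462, 3678, 1335 and 1187 genes and pAKI against controls 988, 767, 1506 and 330, genes changed the same way in OSOM numbered 322, and glomeruli gave 17 for iAKI against controls and 1 for iAKI against pAKI. With DESeq2, pAKI against controls gave 863, 642, 1667 and 691, genes changed the same way numbered 325, 364, 802 and 311, and glomeruli gave 279 for iAKI against controls, 18 for pAKI against controls and 357 for iAKI against pAKI. DESeq2 gave 21 genes whose pAKI change differs between OSOM and cortex and 706 between OSOM and ISOM. With limma-voom and quality weights, pAKI against controls gave 977, 2112, 2458 and 4006, genes changed the same way numbered 343, 1138, 809 and 1470, whole kidney gave 5161 for iAKI against controls and 5647 for iAKI against pAKI, and glomeruli gave 0 for iAKI against controls and 83 for iAKI against pAKI. Limma-voom gave 54 genes whose pAKI change differs between OSOM and cortex and 1044 between OSOM and ISOM. It reversed 1 named gene among those past the test in either fit, Pdk4 in OSOM for iAKI against pAKI, with -0.0287 (adjusted p = 0.965). With no filter, glomeruli gave 143 for iAKI against controls, 2 for pAKI against controls and 214 for iAKI against pAKI.

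With the animal set as a term, pAKI against controls gave 233 in OSOM and 269 in whole kidney, genes changed the same way in OSOM numbered 162, iAKI against pAKI gave 1990 in ISOM, and glomeruli gave 1 for iAKI against controls and 1 for iAKI against pAKI. With set 1 animals only, pAKI against controls gave 974, 918, 472 and 2975. These fits hold no iAKI library, while the fits of set 2 do, so their counts do not differ by set alone. The set 1 counts lay near those with only the arms compared in cortex and OSOM, but not in ISOM and whole kidney. With set 2 animals only, iAKI against controls gave 2, 1290, 752 and 245, pAKI against controls 0, 0, 0 and 7, iAKI against pAKI 20, 1358, 5 and 766, and genes changed the same way numbered 0, 0, 0 and 1. With the library number series as a term, iAKI against controls gave 1038 in cortex and 1573 in ISOM, pAKI against controls 68 in OSOM, and genes changed the same way numbered 35, 50 and 301 in cortex, OSOM and ISOM. With the set acting in each region, 477 genes differed in their iAKI change between ISOM and cortex and 1 in its pAKI change between OSOM and cortex. With an estimated correlation, 9 of the 216 list tests between arms that passed still did.

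The replicate numbers name animals and do not pair them across arms (correlations of same-number pairs -0.222 to 0.196). With the number as a replicate block, iAKI against controls gave 106, 3738, 724 and 1371, pAKI against controls 28, 34, 601 and 10, iAKI against pAKI 1938 in cortex and 1580 in ISOM, and genes changed the same way numbered 7, 25, 208 and 8. The fit across regions had the animal as its block, not this number. With the animal block dropped, the regions of an animal are taken as separate animals. The iAKI change then differed in 64 genes between OSOM and cortex, 253 between ISOM and cortex and 1456 between OSOM and ISOM. The pAKI change differed in 246 between ISOM and cortex and 25 between OSOM and ISOM.

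With 1 library left out, iAKI against controls in cortex ranged from 1012 to 4477 (without Control 3 1679, Control 4 1012, Control 5 1303, iAKI 1 1352, iAKI 2 1226, iAKI 3 4477), in OSOM from 5007 to 6910, in ISOM from 1943 to 2975, in whole kidney from 1581 to 2577 (Control 3 1686, Control 4 1581) and in glomeruli from 1 to 33 (Control 1 11, Control 4 1, iAKI 2 3, iAKI 3 33). For pAKI against controls the range was 4 to 142 in cortex (Control 3 4, Control 4 4, Control 5 142, pAKI 1 78, pAKI 2 31, pAKI 3 126, pAKI 4 48, pAKI 5 110), 17 to 82 in OSOM (Control 3 17, Control 4 23, Control 5 64, pAKI 1 57, pAKI 2 41, pAKI 3 82, pAKI 4 54, pAKI 5 57), 380 to 963 in ISOM (Control 4 459, Control 5 380, pAKI 2 534, pAKI 4 455, pAKI 5 460), 9 to 571 in whole kidney (Control 3 9, Control 4 12, Control 5 571, pAKI 1 61, pAKI 2 51, pAKI 3 64, pAKI 4 40, pAKI 5 57) and 0 to 4 in glomeruli (pAKI 3 4). For iAKI against pAKI it was 2045 to 4645 in cortex (iAKI 1 2045, iAKI 2 2120), 4878 to 7308 in OSOM, 1325 to 3332 in ISOM (iAKI 1 1325), 2064 to 3743 in whole kidney (iAKI 3 2064) and 2 to 25 in glomeruli (iAKI 2 2, iAKI 3 25, pAKI 3 3, pAKI 5 4).

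For genes changed the same way, the range with 1 library left out was 1 to 258 in cortex (Control 3 2, Control 4 1, Control 5 47, pAKI 1 30, pAKI 2 13, pAKI 3 49, pAKI 4 20, pAKI 5 46, iAKI 3 258), 16 to 270 in OSOM (Control 3 16, Control 4 20, Control 5 48, pAKI 1 44, pAKI 2 34, pAKI 3 62, pAKI 4 43, pAKI 5 47, iAKI 1 201, iAKI 2 270), 232 to 634 in ISOM (Control 4 247, Control 5 232, pAKI 2 281, pAKI 4 275, pAKI 5 259) and 5 to 232 in whole kidney (Control 3 5, Control 4 9, Control 5 232, pAKI 1 36, pAKI 2 31, pAKI 3 36, pAKI 4 25, pAKI 5 35, iAKI 1 185). For differences between regions, 1 animal with all its libraries was left out at a time. In the iAKI change the range was 480 to 1908 for OSOM against cortex (Control 3 511, Control 4 707, iAKI 1 758, iAKI 2 1908, iAKI 3 480), 525 to 1289 for ISOM against cortex (Control 4 525, iAKI 1 745) and 2301 to 4043 for OSOM against ISOM. In the pAKI change it was 0 to 1 for OSOM against cortex (Control 5 1), 642 to 1436 for ISOM against cortex (Control 4 778, Control 5 869, pAKI 2 942, pAKI 4 642, pAKI 5 797) and 53 to 314 for OSOM against ISOM (Control 4 195, Control 5 53, pAKI 2 153, pAKI 4 130, pAKI 5 127). Between control regions, again with 1 animal left out, it was 4338 to 5743, 7841 to 8913 and 8730 to 8880.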

Other observations

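The list tests in this part were set down beforehand, no test was chosen after its result was seen, and they are tests, not predictions. In iAKI ISOM, immediate early genes were higher for 2 of 19 (9 over the list alone, adjusted p = 0.0011, and 0.617 with an estimated correlation). The circadian output gene Dbp was higher in iAKI than in pAKI ISOM, 30.5 ± 6.99 against 5.63 ± 3.74 CPM (log2 2.42). Gem, a small GTPase, was lower there, 30.8 ± 17.9 against 207 ± 51.0 CPM (-2.74). In pAKI ISOM, glucocorticoid response genes were higher for 3 of 16 (adjusted p = 0.00959, estimated 0.655), with Cdkn1a (3.08), Ddit4 (1.44) and Arrdc2 (1.02), and Nrf2 targets for 3 of 17 (0.0228, estimated 0.655), with the reductase Nqo1 (1.02).

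In glomeruli, cytokine and acute-phase genes had 0 of 22 called in iAKI against controls and 13 higher over the list alone (adjusted p = 4.01e-16, and 0.290 with an estimated correlation). Interferon response genes had 0 of 20 called and 5 lower over the list alone (1.11e-09, estimated 0.422), and podocyte markers 0 of 12 (0.768). In pAKI glomeruli thick ascending limb markers had 0 of 14 called and 5 higher over the list alone (3.78e-08, estimated 0.754).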
